A study of Mus musculus with 7 samples.

How the data were processed

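CUT&RUN libraries for JUNB were made from an inducible MGT mouse embryonic fibroblast line at day 1, with 2 siControl and 2 siChst7 libraries. A further 3 IgG libraries (1 siControl and 2 siChst7) are among the 7 samples and were not analysed here. The submitters' processing notes name Bowtie2, MACS3 and the genome build mm10, without versions or settings, and whether an IgG library served as control for peak calling is not given in the sources used here. Per the peak names in the deposited files, peaks were listed for each library separately. Each list was matched to its library by those names, which carry the siRNA, the antibody, the day and the replicate number. The treatment protocol in the labels names siJunb, against the gene of the mapped protein, and siH1f0 beside siControl, and does not name siChst7. The groups follow the titles and the treatment labels.

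Each deposited peak has a start, an end, a summit, a fold enrichment over local background, which is a ratio the authors' peak caller gave, and its p-value and q-value as −log10 in the deposited lists. The lowest −log10 q in each list was near 2, so that the lists end near a q of 0.01. Fold and q are the authors' values for single peaks and were used to describe, rank and filter peaks within a list. Read counts per region were not used here, so binding strength was not compared between libraries and a region missing from a list can hold signal below that list's threshold. The labels state 30 M reads for a library; the depth of each library is unknown here, and intervals cover counting error only.

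Peaks of the 4 lists that overlapped by at least 1 bp were joined into regions. A region counted for a group when both libraries had it. Group-only regions were called in both libraries of a group and in neither library of the other, and were set beside the same count for every other pair of libraries. Coordinates are 1-based on mm10. Genes came from an NCBI RefSeq table of GRCm38.p6, the same assembly as mm10, with 21900 protein-coding genes. The table gives no strand, so transcription start sites, which the plan called for, were replaced by either gene end: a region went to the gene with the nearest end within 100 kb, and the share near promoters became the share within 1 kb of a gene end. All 351 entries in the 18 gene lists matched the table, and some genes stand in more than 1 list (Ccn1 and Ccn2 among TGF-beta and Hippo genes, for example). No genome sequence was used here, so the planned AP-1 and other motif searches were not run.

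Numbers of peaks and gene-end shares were compared by two-sided exact permutation of the 4 libraries, which cannot give a p below 0.333. Gene lists were tested in each group against 10000 random lists of the same size, matched on deciles of the length of genome nearest to each gene, with two-sided p-values and Benjamini-Hochberg adjustment over the 18 lists; the smallest p these permutations can give is 0.0002. Lists were compared between groups by Fisher's exact test with the same adjustment. The procedure was tested on simulated peak lists over 21900 genes. It recovered 2485 of 2485 shared, 190 of 190 siControl-only and 402 of 402 siChst7-only regions. These counts were fixed in advance, because each simulated region stood in every library of its class and apart from all others. They do not show how well the classes hold in lists of unequal length. For gene lists, the procedure found 3 of 3 planted lists in each group and called 0 of 28 others. The 28 leave out the list that was given simulated siChst7-only regions. Regions were planted at the starts of many genes of the planted lists, so finding these lists was nearly certain. The procedure called 0 of 360 tests in 20 draws without planted lists. Unplanted regions lay around genes drawn at random, so these counts do not cover regions that gather at active genes.

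Named regions followed a rule fixed with the lists, the tests and most alternatives before the data were examined: the 10 shared regions with the best mean rank, the 10 best regions of each group-only class, Chst7 and the AP-1 family, and up to 4 examples per gene list. Some items that the rule names are not reported here. Genes with the most regions, genes with none and the lists of members with a region were described in addition after their values were seen. Alternatives were 50% reciprocal overlap, summits with 100 bp on each side, a q of at most 0.001, a fold of at least 5, equal list length by rank, autosomes and X, leaving out each library, a replicate block, a gene-end window of 2.5 kb, and gene assignment within 20 kb or to gene bodies with 5 kb on each side. Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.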

Results

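JUNB, a subunit of the transcription factor AP-1, was mapped by CUT&RUN in mouse embryonic fibroblasts that carry a doxycycline-inducible set of the cardiac transcription factors Mef2c, Gata4 and Tbx5 (MGT) and a Myh6-eGFP reporter. CUT&RUN releases DNA around an antibody-bound protein with a tethered nuclease, so that sequenced fragments mark where the protein sat. By the sample titles, cells were transfected with a control siRNA (siControl) or an siRNA against Chst7 (siChst7), a sulfotransferase of chondroitin sulfate. The treatment protocol in the labels names siJunb and siH1f0 beside siControl in place of siChst7, and a knockdown of Junb would lower the mapped protein itself. Cells were collected at day 1 after MGT induction. The question is whether JUNB sits at other places in the genome when Chst7 is targeted during early cardiac reprogramming. Peak lists of 4 JUNB libraries were used, 2 for each siRNA. The 3 IgG libraries were not analysed here, so no antibody background stands beside the values. The labels state 30 M reads for a library, and read depth per library could not be measured from peak lists. The labels call the libraries biological replicates without saying whether cultures were separate. Permutation p-values over the 4 libraries measure the spread between these samples, which may be technical. Gene list p-values come from random genes or from counts of regions and hold no spread between libraries. No expression values were at hand, so the level of Chst7 in either group is not known here.

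Joining overlapping peaks gave 12655 regions, of which 2785 (22.0%) were called in all 4 libraries and 5913 (46.7%) in a single library. The common regions belonged to 1823 of 21900 protein-coding genes by nearest gene end. The genes with the most common regions were Arid5b, Bach2, Capn2, Cd44, Irf2bp2 and Lpp with 6 each. Klf6, Myh9 and Col4a2, a basement membrane collagen, had 5 each. These counts were not corrected for the length of genome nearest to each gene, which was 76.3 kb for Capn2 and 400 kb for Lpp. Among the 10 best-ranked common regions, a region inside Commd10 (chromosome 18, 46997562 to 46998408, mm10) had fold enrichments of 55.0, 81.3, 101.5 and 91.0 in the authors' siControl and siChst7 lists, in replicate order. A region 27.2 kb from Tmem230 (chromosome 2, 132211568 to 132212910) had 41.2 to 63.3, and a region inside Src, a tyrosine kinase of adhesion signalling (chromosome 2, 157447102 to 157448924), had 33.5 to 78.5. Regions 5.1 kb from Eef1g (chromosome 19, 8981156 to 8985069) and inside Cd109 (chromosome 9, 78622924 to 78623999) completed the 5 high-fold members. The other 5 lay more than 100 kb from any protein-coding gene end and had folds of 1.27 to 3.05. They were a region at chromosome 2, 98666635 to 98667220, 3 regions near the start of the chromosome 9 assembly, and a region at chromosome 14, 19416940 to 19417919. The chromosome 2 region had a −log10 q of 6683 to 9701 in the 4 lists, against 269 to 450 for the high-fold Commd10 region. Whether these 5 low-fold regions mark JUNB or background was not tested, since the IgG libraries were not analysed here. Exon and intron positions were not used here.

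**Figure D1:**
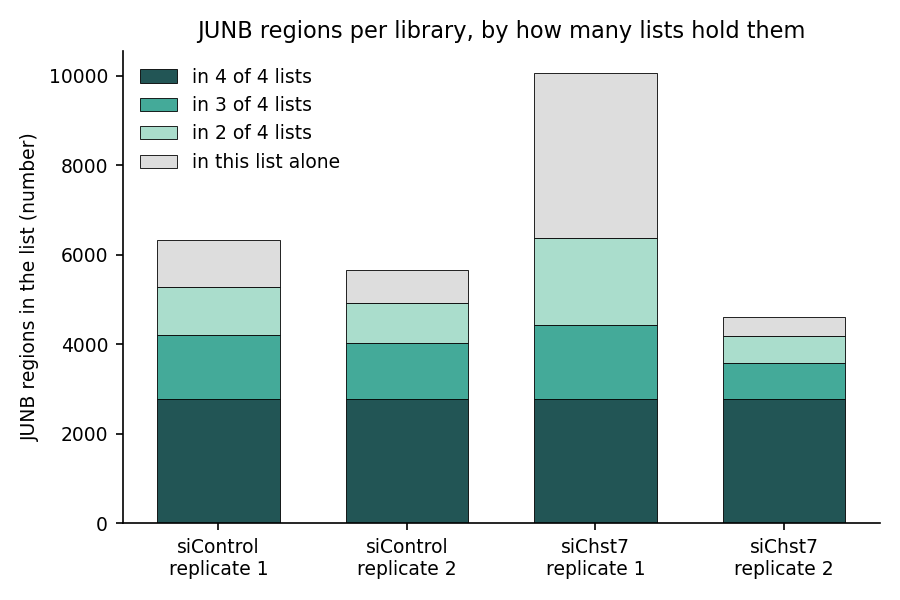
Bars give the number of JUNB regions in each of the 4 libraries (y axis), stacked by how many of the 4 lists hold the region. The 2785 regions in all lists form the base of every bar, and siChst7 replicate 1 alone holds 3692 regions found in no other list.

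The libraries differed in list length more within the siChst7 group than between groups. The siControl lists held 6469 and 5827 peaks (mean 6148 ± 454, SD, n = 2) and the siChst7 lists 10163 and 4735 (mean 7449 ± 3838, SD, n = 2). The difference of the mean log2 numbers, siChst7 minus siControl, was 0.18, and the two-sided exact permutation p was 1, in a design whose smallest possible p is 0.333. Without siChst7 replicate 1 the difference was −0.37.

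Fibroblast identity genes were near JUNB regions more often than matched random genes in both groups. Of 34 fibroblast identity genes, 17 owned a region called in both siControl libraries and 14 a region called in both siChst7 libraries, against means of 5.66 and 5.74 in 10000 random lists matched on gene territory (permutation test with Benjamini-Hochberg adjustment over 18 lists, adjusted p = 0.0009 and 0.00514). In both groups these included Col1a1, Col5a1, Col5a2, Thy1, Fbn1, Loxl1, Snai1 and Zeb2. A region 9.9 kb from Fbln2, which encodes an extracellular matrix glycoprotein (chromosome 6, 91201878 to 91203255), had folds of 30.4 to 36.6 in the 4 lists. A region 0.6 kb from Vim, the intermediate filament gene (chromosome 2, 13572724 to 13574471), had 18.7 to 25.4. Col3a1, Pdgfra, Dcn, Lum, Fbln1, Twist1, Snai2, Fap and Mmp2 owned no region in any library. When regions were instead given to every gene body within 5 kb, the fibroblast count in siChst7 was 9 (permutation, adjusted p = 0.125).

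The TGF-beta and myofibroblast list had 13 of 26 genes with a region in each group, against random means of 3.39 and 3.48 (permutation test, adjusted p = 0.0009 in each). Smad3, a signal transducer of TGF-beta, had 3 common regions. A region 18.9 kb from the integrin gene Itgb1 (chromosome 8, 128666260 to 128667446) had folds of 23.1 to 31.1, and a region inside Itgav (chromosome 2, 83727980 to 83729068) had 9.8 to 18.3. Acta2 and Tagln, markers of contractile myofibroblasts, owned none. Immediate-early and MAPK feedback genes gave 13 of 22 in siControl and 12 of 22 in siChst7, against 3.00 and 3.07 (permutation, adjusted p = 0.0009 in each). Klf6 had 5 common regions, and Myc, Hbegf and Dusp1, a phosphatase that switches off MAP kinases, had 4 each. A region 75.3 kb from Phlda1 (chromosome 10, 111582911 to 111584479) had folds of 18.3 to 35.9.

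**Figure D2:**
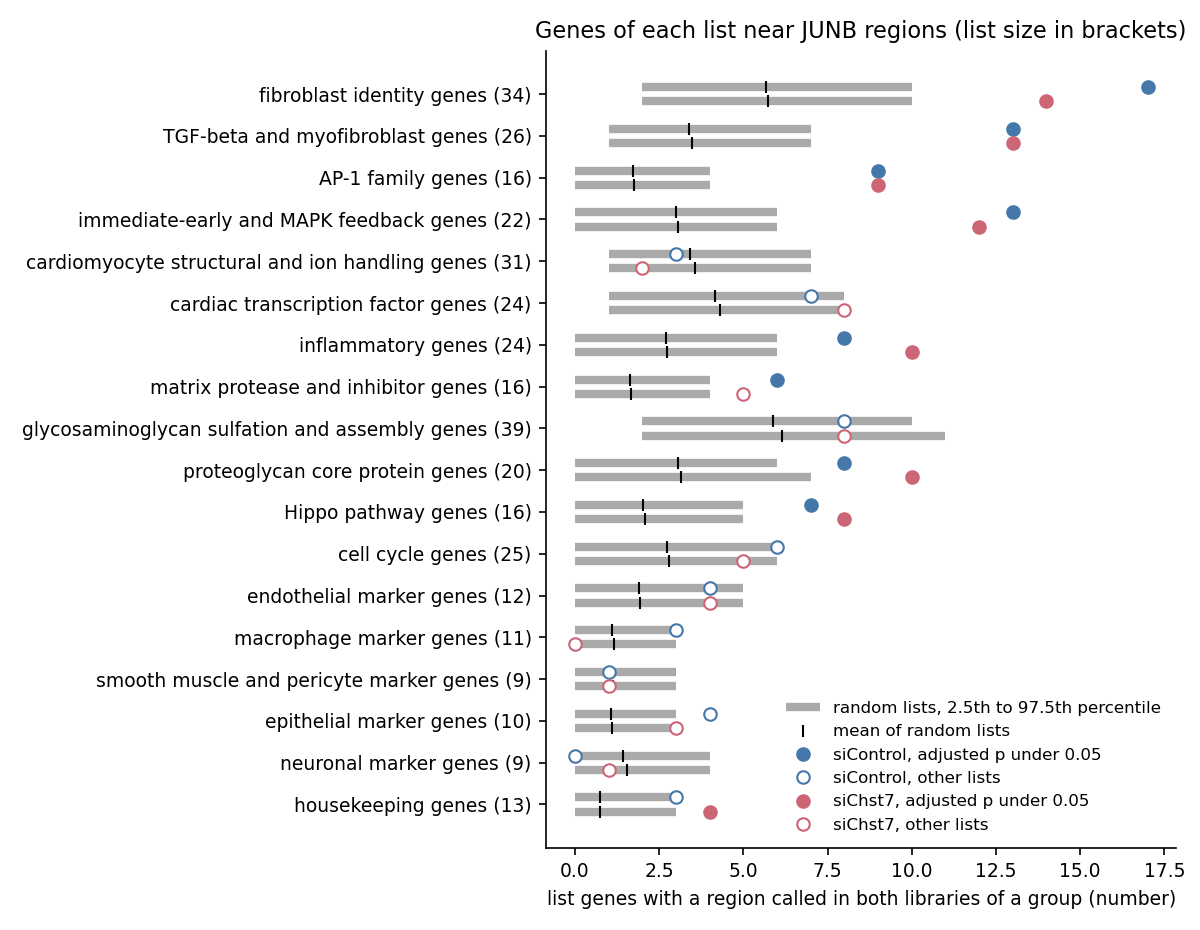
Points give, for 18 gene lists, how many genes own a region called in both siControl or both siChst7 libraries (x axis), filled where the adjusted permutation p is under 0.05; grey bars span the central 95% of random lists and ticks their mean. The 17 and 14 fibroblast identity genes lie to the right of the random range of 2 to 10.

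Inflammatory, proteoglycan and Hippo pathway genes also passed the permutation test in both groups. Inflammatory genes gave 8 and 10 of 24 (permutation, adjusted p = 0.017 in siControl and 0.0009 in siChst7), among them Nfkbia and Tnfaip3, which restrain NF-kB, each with a common region. Proteoglycan core protein genes, whose products carry the sulfated chains that sulfotransferases modify, gave 8 and 10 of 20 (permutation, adjusted p = 0.0265 and 0.00144). Cd44 had 6 common regions, and a region inside Sdc4 (chromosome 2, 164438505 to 164439862) had folds of 10.8 to 22.5. Hippo pathway genes gave 7 and 8 of 16 (permutation, adjusted p = 0.0115 and 0.0018), with 4 common regions for Tead1 and 3 for Ankrd1. Matrix protease and inhibitor genes passed in siControl (6 of 16, permutation, adjusted p = 0.0162) and not in siChst7 (5 of 16, adjusted p = 0.0728). Housekeeping genes passed in siChst7 (4 of 13, permutation, adjusted p = 0.022) and not in siControl (3 of 13, adjusted p = 0.108). The proteoglycan call ended when any of siControl replicate 1, siControl replicate 2 or siChst7 replicate 2 was left out (permutation, adjusted p = 0.124, 0.159 and 0.148 in the group concerned). Gene assignment within 20 kb ended the inflammatory calls (permutation, adjusted p = 0.103 and 0.760), 50% reciprocal overlap ended the Hippo calls (0.0895 and 0.0771) and the siControl proteoglycan call (0.0545), summit windows ended the siControl Hippo call (0.0886), and gene bodies with 5 kb ended the calls of these 3 lists except Hippo in siChst7. The matrix protease list passed in siControl in 8 of 13 alternatives and in siChst7 in 4 of 13 (lowest adjusted permutation p = 0.0009), and the housekeeping call in siChst7 held in 11 of 13.

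Glycosaminoglycan sulfation and assembly genes, the family of Chst7, did not pass: 8 of 39 owned a region in each group, against random means of 5.88 and 6.16 (permutation test, adjusted p = 0.495 and 0.671). Chst1, Chst3, Chst11, Ust, Ndst1, Ext1 and Sulf1 were the members with a region in both groups. A region 63.4 kb from Chst1 (chromosome 2, 92678006 to 92679088) had folds of 16.7 to 31.9. Chst7 itself (chromosome X, 20058963 to 20099991) owned no region, and the nearest, called in 1 list, lay 279 kb away. The cell cycle list gave 6 and 5 of 25 (permutation, adjusted p = 0.152 and 0.382). Marker lists of other cell types did not pass in either group, but with 9 to 12 genes each they gave the tests little to work with. In siControl and siChst7, 4 and 4 of 12 endothelial, 3 and 0 of 11 macrophage and 1 and 1 of 9 smooth muscle genes owned a region. Epithelial genes gave 4 and 3 of 10, and neuronal genes 0 and 1 of 9. Random means ran from 1.07 to 1.89 in siControl and from 1.10 to 1.93 in siChst7. The epithelial counts were 3.75 and 2.73 times their random means, against 3.00 and 2.44 times for the fibroblast list. The epithelial list passed in siControl in 3 of 13 alternatives (lowest adjusted permutation p = 0.0382).

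Most AP-1 family genes owned JUNB regions. In each group 9 of 16 had a region in both libraries, against random means of 1.73 and 1.76 (permutation test, adjusted p = 0.0009 in each), and these were Jun, Fosb, Fosl1, Fosl2, Atf3, Maf, Maff, Mafk and Jdp2. A region 32.9 kb from Atf3, a stress-induced family member (chromosome 1, 191215833 to 191216908), had folds of 11.2 to 20.0. A region 28.5 kb from Jdp2 (chromosome 12, 85569892 to 85570900) had 8.2 to 12.6. Regions near Jund, Fos and Atf2 were called in siChst7 replicate 1 alone, and Junb had 2 regions in siControl replicate 1, 2 in siChst7 replicate 1 and 0 in the other libraries. Batf and Batf3 owned none. Around Jun, regions at chromosome 4, 95084249 to 95084621 and 95105207 to 95106331, were in all 4 lists. A region at 95035365 to 95035775 was in the siControl lists, and one at 95100596 to 95100895 was in the siChst7 lists. With regions given to gene bodies within 5 kb, the siChst7 count was 3 (permutation, adjusted p = 0.393).

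**Figure D3:**
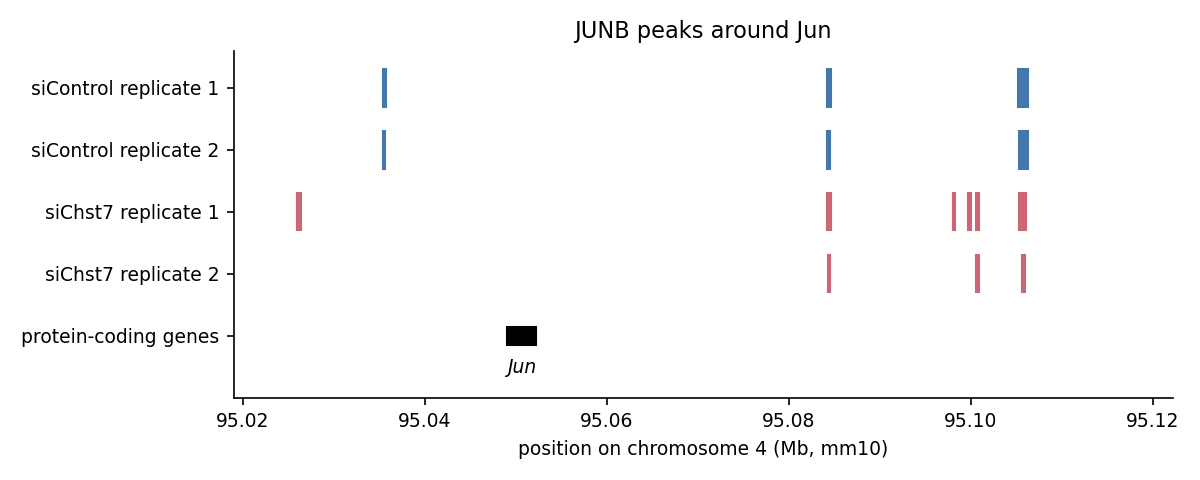
Boxes mark JUNB peaks of each library (rows) along chromosome 4 around Jun (x axis, Mb, mm10), with the gene at 95049036 to 95052222 in black. The peaks near 95084249 and at 95105207 to 95106331 are in every row, and the peak near 95100596 is in the siChst7 rows.

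Few cardiomyocyte genes were near JUNB regions. Of 31 cardiomyocyte structural and ion handling genes, 3 owned a region in siControl and 2 in siChst7, near the random means of 3.42 and 3.55 (permutation test, adjusted p = 1 and 0.674). Gja1, which encodes connexin 43, and Casq2, the sarcoplasmic reticulum calcium-binding protein, were those in both groups, and 25 genes, Myh6 among them, had no region in any library. Cardiac transcription factor genes gave 7 and 8 of 24 (permutation, adjusted p = 0.276 and 0.182). Gata4, Gata6, Mef2a, Mef2c, Mef2d and Myocd each had a common region, and Tbx5 had none. A region 96.2 kb from Myocd, a cofactor of serum response factor (chromosome 11, 65365446 to 65367056), had folds of 12.5 to 20.8. Whether the cardiac lists differ from the fibroblast list was not tested.

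Regions that separated the siRNA groups were few beside those they shared. Of 3942 regions called in both siControl libraries, 70.6% (exact Clopper-Pearson interval 69.2 to 72.1, counting error only) were called in both siChst7 libraries, and of 4011 regions called in both siChst7 libraries, 69.4% (68.0 to 70.9) were called in both siControl libraries. There were 203 siControl-only regions, called in both siControl lists and neither siChst7 list, and 491 siChst7-only regions. The best-ranked siControl-only regions were nearest to Myo5a, Meox1, Lrrk2, Rmdn2, Dtd2, Mitf, Gm10461, Mrgprd, Igf1 and Pax8. The region inside Myo5a (chromosome 9, 75124293 to 75124562) had folds of 9.7 and 9.9, and that inside Igf1, a growth factor gene (chromosome 10, 87879928 to 87880545), 8.0 and 7.1. Among the best siChst7-only regions were those nearest to Galntl6, Rai14, Tmco5, Pacsin2, Vps37c, Cebpb, Psmc3, Epb41l4a and Cdkn2b. The region inside Galntl6 (chromosome 8, 57800130 to 57800534) had folds of 10.2 and 10.1. The regions nearest to Cebpb, Epb41l4a and Cdkn2b lay 110.5, 136.5 and 129.2 kb from the gene end. With 50% reciprocal overlap the regions nearest to Lrrk2, Igf1, Pax8, Psmc3 and Cdkn2b were in 1 list, and the other group-only regions named so far kept 2. Summit windows left those nearest to Pacsin2 and Epb41l4a in 1 list. The Mrgprd region had a fold of 2.29 in both siControl lists. A siChst7-only region 28.3 kb from Ccl2, a monocyte chemokine gene (chromosome 11, 82007047 to 82007448), had folds of 5.8 and 5.7, and Ccl2 also had 3 common regions.

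Mixed pairs with siChst7 replicate 1 held more regions of their own than the siRNA pairs, and the other mixed pairs held fewer. The pair of siControl replicate 1 and siChst7 replicate 1 held 811 regions found in neither other list, and siControl replicate 2 with siChst7 replicate 1 held 640. With siChst7 replicate 2, siControl replicate 1 held 70 and siControl replicate 2 held 53, against 203 for the siControl pair. The Jaccard index is the share of regions common to a pair among all regions of the pair. It was 49.0% for the siControl pair, 37.6% for the siChst7 pair and 41.4% to 44.6% for mixed pairs. Its mean was 43.3% within groups and 43.5% between groups, a difference of −0.14 percentage points. Of the 3 splits into pairs, 2 gave a value as large (smallest possible exact p 0.333). At equal list length the direction turned: the difference was 2.45 points, with 294 siControl-only and 331 siChst7-only regions. Leaving out 1 library moved the siControl-only count to between 256 and 1274 and the siChst7-only count to between 771 and 4204. A region then needs 1 library where its own group lost one, or to be missing from 1 library where the other group did.

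**Figure D4:**
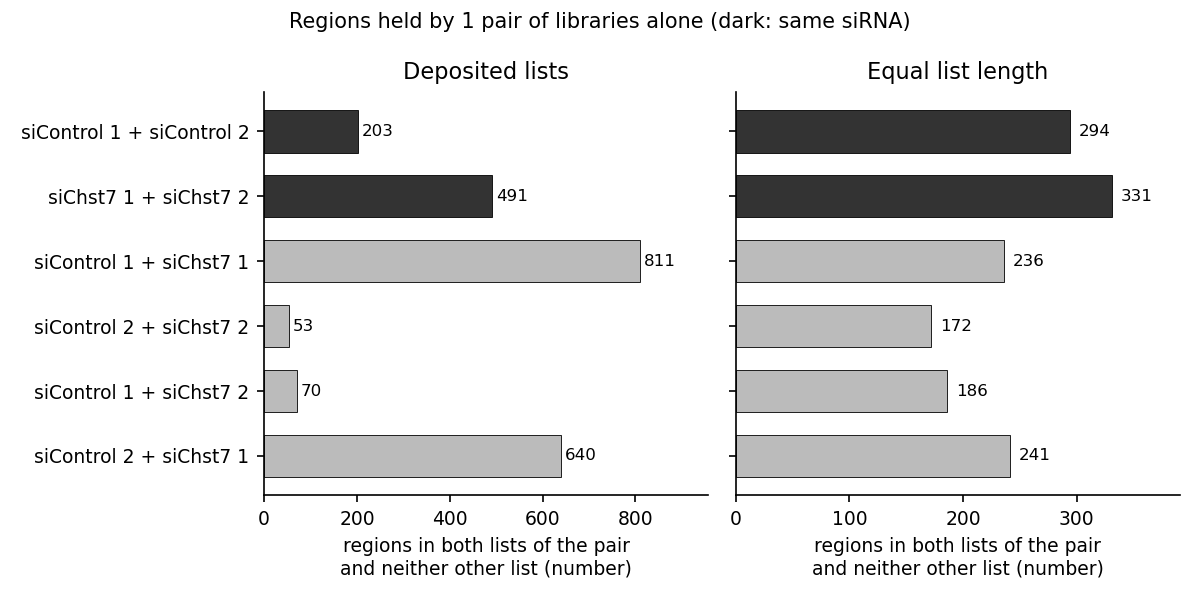
Bars give the number of regions held by both libraries of a pair and by neither other library (x axis) for the 6 pairs, with the deposited lists on the left and equal list length on the right; dark bars are pairs of the same siRNA. The siChst7 pair holds 491 regions against 811 for siControl replicate 1 with siChst7 replicate 1, and at equal length the dark bars, 294 and 331, are the longest.

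No gene list was found to separate the groups, but the comparison had few regions to work with. Lists held at most 3 siControl-only regions (TGF-beta and macrophage) and 4 siChst7-only regions (Hippo). Lists with 0 of both, such as immediate-early and cell cycle genes, could not pass. Of 18 lists, 0 passed the adjusted threshold when regions of list genes were compared between siControl-only and siChst7-only regions (Fisher's exact test, two-sided), and 1 had an unadjusted p under 0.05. That list was the macrophage markers, with 3 siControl-only regions, nearest to Cd68, Itgam and Cd14, and 0 siChst7-only regions (Fisher's exact test, p = 0.0248, adjusted p = 0.446). Without siChst7 replicate 2 the macrophage list passed, with 3 and 1 regions (Fisher's exact test, adjusted p = 0.0129). Among fibroblast identity genes, 2 siControl-only regions belonged to Col1a1 and Tcf21 and 2 siChst7-only regions to Col5a2 and Zeb2 (Fisher's exact test, adjusted p = 1). The tests compare region sets of these libraries, not independent cultures.

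Most JUNB regions lay away from gene ends. The share of peaks with a summit within 1 kb of either end of a protein-coding gene was 10.9% and 9.51% in siControl (mean 10.2% ± 0.972, SD, n = 2) and 11.4% and 9.12% in siChst7 (mean 10.3% ± 1.62, SD, n = 2), against 4.27% to 4.49% for the same summits moved by 500 kb. The groups differed by 0.07 percentage points (two-sided exact permutation p = 1, smallest possible 0.333). At equal list length the difference was −0.46. Between 52.5% and 53.1% of summits lay inside a gene. Near gene ends were 26 of 203 siControl-only and 53 of 491 siChst7-only regions (Fisher's exact test, p = 0.434), and 7.90% of common regions.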

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

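The alternatives without peaks under 3-fold, with the best 1000, 2000 or 3000 peaks, without regions within 2.5 kb of a gene end, and with an exact McNemar test over genes were chosen after seeing the data. The motif results were not run. The count of shared regions and the count of lists apart between groups stayed within 1.5 times or at 0 under the alternatives computed for them, which leave out the best 1000, 2000 and 3000 peaks, except that 1 list passed without siChst7 replicate 2. The within-group minus between-group Jaccard difference (−0.14 points) became 0.0955 with 50% reciprocal overlap, 0.132 with summit windows, 0.0873 with q of at most 0.001, 1.09 with fold of at least 5, 2.45 at equal list length, and 2.33, 2.24 and 2.36 with the best 1000, 2000 and 3000 peaks; the cause was not tested. The siControl-only count moved to 313 with reciprocal overlap and 332 with summit windows. In the same order the siChst7-only count was 453 and 538, the shared count 1917 and 1883, and the retained share 61.1% and 57.7%. With fold of at least 5 the retained share was 68.1%. The gene-end difference became −0.46 at equal list length. Lists above chance, 16 in the 2 groups together, numbered 10 with gene bodies and 5 kb, and 12 to 17 under the other alternatives that kept all 4 libraries. Smaller windows split regions by construction; for the other shifts the cause was not tested.

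Leaving out 1 library gave ranges of −0.37 to 0.73 for the log2 peak number difference, −6.16 to 6.60 for the Jaccard difference, 256 to 1274 siControl-only regions, 771 to 4204 siChst7-only regions, 51.0% to 93.5% for the retained share, −1.07 to 1.22 points for the gene-end difference, and 0 to 1 for lists apart, where 1 library then stands for its group. Replicate numbers are shared between groups, but differences between replicates 1 and 2 did not go together over regions (correlation −0.03, and −0.01 at equal length), so the numbers were not taken to pair libraries. With the replicate block the Jaccard difference was −0.67 and the retained share 67.1%; no count changed, by construction for region sets. Of 468 gene list tests under alternatives, 438 kept their side of the threshold, 23 lost it and 7 gained it. Of 210 checks of the named regions, 190 gave the same number of lists.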

Other observations

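All tests of explanations here were chosen after the pattern was seen, except that of the best 2000 peaks and that without regions near gene ends, which were written before their values were known. For 3 explanations the first test was replaced after its value was known, because it could not decide. The shorter siChst7 list, 4735 peaks, had been read against a gain common to both siChst7 libraries. The ratio at equal list length, 1.13, had been read for list length, although cutting the lists to equal length can lower it under other causes too. The lowest adjusted p of the neuronal, macrophage, smooth muscle and endothelial lists, 0.265, and then the pool of these 4 lists had been read against a general excess, leaving out the epithelial and housekeeping lists.

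Single members of the cell cycle and cell type lists had common regions. Mdm2, which restrains p53, had a region 10.7 kb from the gene end (chromosome 10, 117721014 to 117722047) with folds of 11.0 to 19.0 in the 4 lists. A region 3.8 kb from Cdkn2b, a cyclin-dependent kinase inhibitor gene (chromosome 4, 89301880 to 89302719), had 9.8 to 11.4. Ccnd1, Cdk6 and Cdkn1a also had common regions. Among markers of other cell types, a region inside the endothelial cadherin gene Cdh5 (chromosome 8, 104121495 to 104122394) had folds of 8.2 to 16.7, and a region 13.6 kb from the keratin gene Krt18 (chromosome 15, 102045146 to 102046191) had 12.7 to 19.0.

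Peaks under 3-fold numbered 55, 59, 47 and 50 in siControl 1, siControl 2, siChst7 1 and siChst7 2. On assembled chromosomes, 80.0% to 89.3% of them lay more than 100 kb from a gene end, against 12.2% to 12.8% of the other peaks (Fisher's exact test, largest p = 4.8e-17). The test takes peaks as independent, but some lie close together, as at the start of chromosome 9, and recur in all 4 lists. Its p thus overstates the evidence. The peaks under 3-fold took 5, 5, 3 and 5 of the 10 best places by q in the same order of libraries. Whether they mark JUNB or background was not tested.

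More regions were siChst7-only than siControl-only, by 2.42 times. The longer list of siChst7 replicate 1 is a candidate explanation that these counts cannot decide. The mixed pairs that held this library owned 9.14 and 15.3 times as many regions as their complements. Each complement held siChst7 replicate 2, which has the shortest list, so high ratios followed from the list lengths. In the split by siRNA both of these libraries stand on the same side. The ratios thus do not tell how much of the 2.42 times comes from list length. Higher read coverage of siChst7 replicate 1 stays open. The background coverage implied by the spacing of its folds, if these were computed as MACS does by default, was 1.26 times the mean of the other 3. However, siControl replicate 1 had the lowest implied coverage and the second longest list. The fitted spacing held for 27.5% of the folds in siControl replicate 1, the lowest share, and for up to 33.2% in the other lists. Implied coverage is thus a rough measure. A gain common to both siChst7 libraries stays open too. The siChst7 pair owned 491 regions against 811 and 640 for the mixed pairs with siChst7 replicate 1, but siChst7 replicate 2 has the shortest list, which lowers its pair's count.

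At equal list length, the siControl pair shared 3131 regions, the siChst7 pair 3117 and the mixed pairs 2867 to 3164. Not every same-siRNA pair thus shared more than every mixed pair. On average, the Jaccard index was 2.45 points higher within groups than between them. Weak peaks at the end of the lists are argued against as the source, since the best 2000 peaks gave a within-group excess of 2.24 points, against −1.01 for the higher of the mixed splits. The split by siRNA gave 625 pair-only regions at equal list length and the highest other split 427. With the deposited lists it gave 694, below the 864 and 710 of the mixed splits. A difference between siControl and siChst7 may underlie the excess at equal length, but 4 libraries make 3 splits, too few for a share under 0.05. A batch shared by the libraries of a group would look the same and the labels give none.

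Fibroblast, TGF-beta, AP-1 and immediate-early lists owned more JUNB regions than random lists. Nonspecific cutting at gene ends is argued against: without regions within 2.5 kb of a gene end, 8 of 8 tests still passed, the weakest at an adjusted p of 0.0483 (fibroblast genes, siChst7). A general excess beyond these 4 lists stays open. It was not seen at every list: cardiomyocyte genes gave 3 in siControl and 2 in siChst7, near random means of 3.42 and 3.55. Inflammatory, proteoglycan and Hippo genes passed in both groups. The pooled genes of the 5 marker lists and the housekeeping list owned regions 2.04 times as often as random lists in siControl and 1.71 times in siChst7. Their upper bounds were 3.11 and 2.71, above the lowest of the 4 lists (3.00 and 2.44). Within that pool the lists went apart, with the epithelial list at 3.75 and 2.73 times and the housekeeping list at 4.05 and 5.36 times, and the other 4 together at 1.45 and 1.04 times. Open chromatin at genes active in fibroblasts was not tested, since the IgG libraries were not analysed here.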
